A study of Homo sapiens with 4 samples.

How the data were processed

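The deposited table holds FPKM (fragments scaled for gene length and library depth) for 60302 genes in 4 samples, 2 controls and 2 hnRNPF knockdown samples of HMLE cells. Per the labels' protocols, total RNA was extracted with Trizol and made into stranded paired-end polyA-selected TruSeq libraries. The submitters' processing notes name STAR 2.5.3a, Cuffdiff 2.2.1 and the GRCh37 build without roles. Which of these tools gave the FPKM, and the annotation release, are not given in the sources used here. Per the file headers each column is 1 replicate of 1 group, and each row gives a symbol, a versioned Ensembl gene identifier and a locus, which supplied the coordinates printed. Samples were assigned to groups from their titles and treatment labels. FPKM are already scaled for depth and gene length, so a gene's value also depends on how fragments were shared among overlapping genes and near-identical copies.

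The FPKM sums were 393977 and 392023 in the controls and 391184 and 396135 in the knockdown samples. Depth was estimated from genes annotated with 1 exon and at least 500 bp, as the commonest lowest step of FPKM times length. Between 46.2% and 49.2% of the low values were whole multiples of that step within 0.02, so whole reads were not recovered and no count test was run. The implied totals are estimates.

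Genes with a mean of at least 1 FPKM over the 4 samples were tested (13110). Values were transformed as log2(FPKM + 1), so fold changes on this scale understate the change of low genes. Fold changes called fold in the text are ratios of mean FPKM, except the simulated changes and the fold threshold of 2, which are on the log2(FPKM + 1) scale. Groups were compared with limma 3.58.1 in R 4.3.3, with an empirical Bayes fit with an intensity trend on all 4 samples and no covariate, and with Benjamini-Hochberg adjustment at 0.05. Tests are two-sided. An exact permutation test of 2 samples against 2 cannot give a p under 0.333, so none is reported. Before the data were examined, 27 gene lists, 18 preset genes and the rule for naming genes were written down. Of these lists 25 had at least 3 tested members and were tested with camera at a preset correlation of 0.01 against all other tested genes. The p-values were adjusted over the lists, and the tests were repeated with an estimated correlation and with fry. With an estimated correlation camera rests on the 2 residual degrees of freedom, so that version has little power. The named genes are HNRNPF, the preset genes, and 10 higher and 10 lower genes. These are the ones with the largest change among genes past the threshold and without overlap between the groups, filled up with the smallest p where fewer passed. For each list the text names up to 4 members past the threshold or else at most the 2 with the smallest p. Pseudogenes, small RNA genes and genes with clone names only were not named.

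The alternatives were pseudocounts of 0.1 and 0.5 FPKM, no filter, a filter at 5 FPKM, quantile normalization, median-ratio scaling, the fit without the trend or with robust estimation, the replicate number as a block, a fold change of at least 2, and leaving out each sample in turn. A correction for GC content and transcript length, made within each sample by splines, was added after seeing the data. GENCODE 29 supplied gene types, transcript sequences and 3′ UTRs for 55692 matched identifiers and no coordinates, since it is on another build. A GC value was had for 98.8% of the tested genes. In a scan of 3′ UTRs, each 7-base sequence present in at least 50 genes was tested for a shift in rank of the log2 fold change, after a cubic trend in 3′ UTR length and GC content was removed, over 11285 protein-coding genes.

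The limma fit was tested on 10 simulated tables with the means of the 13110 genes, their spread as moderated by that fit, and 200 changed genes. Noise was independent between genes and held no effect of the replicate number. It recovered 59.6% of 2-fold, 95.7% of 4-fold and 97.7% of 8-fold changes, with 10.2 false calls per table on average. In the same tables camera called a list of 30 genes shifted by -0.2 in 10 of 10 runs and 0 of 240 unshifted lists. Genes were simulated as independent, so this does not measure false calls for lists of correlated genes. The 7-base scan placed a sequence given a shift of -0.05 at the lowest z in 10 of 10 simulated runs; a larger shift had been tried first. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for sequence tests and figures.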

Results

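PolyA-selected RNA from 4 cultures of HMLE cells, an immortalized line of human mammary epithelial cells, was sequenced as stranded paired-end libraries. In 2 samples the cells stably expressed a non-specific short hairpin RNA delivered by lentivirus (control), and in the other 2 a hairpin against HNRNPF (hnRNPF knockdown). HNRNPF encodes hnRNP F, an RNA-binding protein that recognises G-rich sequence and regulates alternative splicing. The series title concerns RNA G-quadruplexes and splicing through this protein. The comparison asks how the polyadenylated transcriptome of the 2 groups differs when hnRNPF is depleted. The table analysed holds 1 FPKM value per gene and sample, so exon usage and isoforms were not analysed here. It lists 60302 genes, of which 13228 and 12664 reached 1 FPKM in controls 1 and 2, and 13390 and 12854 in knockdown samples 1 and 2. Fragment totals are not listed. The lowest steps in the values of single-exon genes imply about 77400000 and 84200000 fragments in the controls and 80600000 and 85000000 in the knockdown samples, if the commonest lowest step is 1 fragment. At that depth 1 FPKM on a gene of 1 kb corresponds to about 77 to 85 fragments. Errors below are SDs with n = 2 per group unless named otherwise. The labels do not say whether the samples of a group came from separate infections or carry different hairpins, so the p-values measure only the spread between these samples.

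HNRNPF (ENSG00000169813.16, chromosome 10, 43881065 to 43904614 on the minus strand, GRCh37) was 8.71-fold lower in the knockdown samples. It stood at 154 ± 0.985 FPKM in the controls (154 and 153 FPKM). It was at 17.6 ± 1.42 FPKM in the knockdown samples (18.7 and 16.6 FPKM). Its log2 fold change of -3.05 (SE 0.0986) had an adjusted p of 0.0251 in limma, and every sample matched its label. The call rested on few samples: the adjusted p was 0.262 without control 1 and 0.104 without control 2, with log2 fold changes of -3.05 and -3.06. It was 0.259 when no filter on low values was used and 0.0995 without the intensity trend, at the same fold change. Among the paralogs of hnRNP F, HNRNPH1 stood at 96.0 and 75.3 FPKM in the controls and at 134 and 117 FPKM in the knockdown samples, 1.47-fold apart. That difference did not pass over all genes (limma, adjusted p = 0.762). In the 5-gene hnRNP F/H family 1 member was higher (HNRNPH1) and 1 lower (HNRNPF) when adjusted over the list alone. HNRNPH3 was at 93.6 ± 16.4 FPKM in the controls and 111 ± 12.8 FPKM in the knockdown samples, with overlapping groups. Single libraries set the values of the other family members. HNRNPH2 was at 41.1 and 45.0 FPKM in the controls and 40.7 FPKM in knockdown 1 but 6.30 FPKM in knockdown 2. It shares its locus with a readthrough gene, RPL36A-HNRNPH2, which was at 3.57 and 1.77 FPKM in the controls and 0.256 and 1.42 FPKM in knockdown. In the sum of both the log2 fold change was -1.29, against -1.33 for HNRNPH2, so a move of values to the readthrough gene does not account for the drop. GRSF1 was at 29.6 and 29.9 FPKM in the controls, 17.5 FPKM in knockdown 1 and 35.1 FPKM in knockdown 2. As a set, the family passed a rotation test of its own genes (fry, adjusted p = 0.0037), but the set holds HNRNPF, so this result includes the knockdown itself. The other 4 genes, tested alone after that result was seen, were 2 higher and 2 lower with a median log2 fold change of -0.000196 (fry toward higher, unadjusted p = 0.035; camera, unadjusted p = 0.449). The family of 5 did not pass the comparison with other genes (camera, adjusted p = 0.28 and adjusted p = 0.657 with an estimated correlation), except without knockdown 2 (adjusted p = 0.0284).

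**Figure D1:**
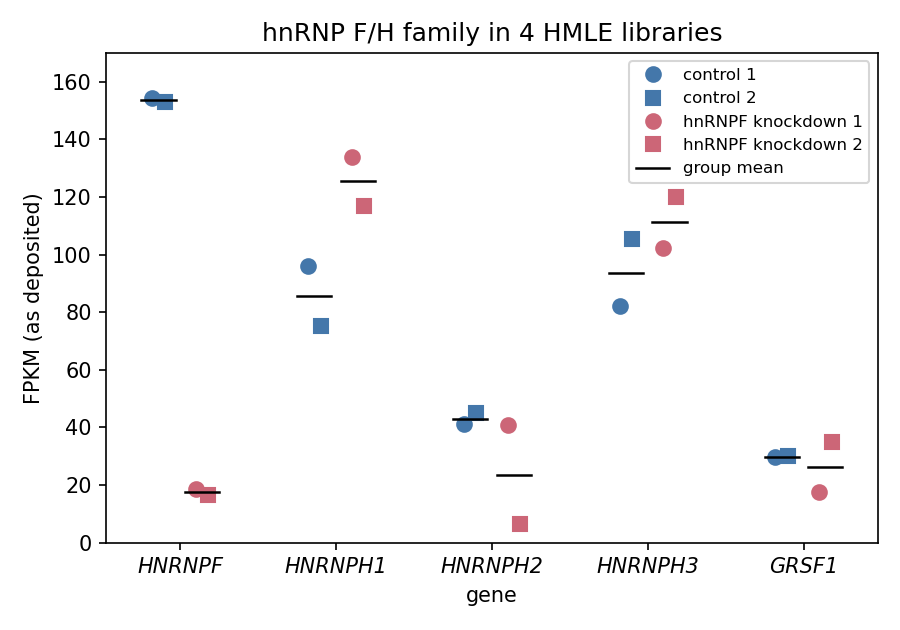
FPKM as deposited (vertical axis, linear) of the 5 hnRNP F/H family genes in each of the 4 libraries; blue points are controls, red points knockdown samples, circles replicate 1, squares replicate 2, and lines the group means. HNRNPF lies at 154 and 153 FPKM in the controls and at 18.7 and 16.6 FPKM in the knockdown samples, while HNRNPH2 is low in knockdown 2 alone (6.30 FPKM).

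HNRNPF was the only gene of the 13110 tested that passed the adjusted threshold of 0.05 in limma, so there were 0 genes upregulated and 1 gene downregulated. The next lowest adjusted p was 0.236. At an unadjusted p under 0.05 there were 401 genes higher and 396 genes lower, 797 in all against 656 expected by chance. With the replicate number as a block, on fewer residual degrees of freedom, 1790 genes lay under 0.05. HNRNPF then had an adjusted p of 0.164 in limma. Both knockdown samples lay on the same side of both controls for 4536 genes (34.6%). Samples that all resembled each other equally would give 33.3%, but a gene can be separated by only 1 division of the samples. The division by replicate number (control 1 and knockdown 1 against control 2 and knockdown 2) separated 50.4%. The crossed division (control 1 and knockdown 2 against control 2 and knockdown 1) separated 14.9%. At an unadjusted p under 0.05 in limma these 2 divisions gave 2423 and 147 genes. In simulated tables with 200 changed genes, the same fit recovered 59.6% of the 2-fold and 95.7% of the 4-fold changes on the log2(FPKM + 1) scale. The simulated noise had the spread as moderated by the empirical Bayes fit, was independent between genes and held no effect of the replicate number. These shares therefore do not show that changes of this size are absent here. The readthrough gene BLOC1S5-TXNDC5 was listed at 42.7 FPKM in knockdown 1 and at 0 in the other 3 samples. Its log2 fold change without knockdown 2 was 5.45. The overlapping TXNDC5 had a log2 fold change of -1.64 over all samples and -0.494 once summed with it. Values may therefore have moved between these genes in knockdown 1.

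The genes with the smallest p after HNRNPF did not pass the threshold and are given as values. Lower in both knockdown samples was UBE2B, a ubiquitin-conjugating enzyme (34.4 ± 0.131 FPKM in the controls, 12.4 ± 0.0467 FPKM in knockdown). CHST11, a chondroitin sulfotransferase, was at 7.32 ± 0.685 and 1.5 ± 0.177 FPKM. Others were HADHB, a subunit of the trifunctional enzyme of fatty acid oxidation (53.6 ± 6.53 and 21.1 ± 1.49 FPKM), and CHCHD3, of the cristae-organising MICOS complex (37.7 ± 3.05 and 14.2 ± 1.23 FPKM). TIMM17B belongs to the inner membrane import machinery (23.6 ± 2.54 and 10.2 ± 0.0457 FPKM), and ECSIT, a complex I assembly factor (23.5 ± 0.166 and 11.9 ± 0.156 FPKM). CCDC25 (20.7 ± 1.34 and 9.80 ± 0.0649 FPKM) and TMEM265 (2.78 ± 0.19 and 0.177 ± 0.0408 FPKM) were also in this group. The readthrough gene INO80B-WBP1 was listed at 7.45 and 5.76 FPKM in the controls and at 0 in both knockdown samples. The summed FPKM of INO80B-WBP1 and the overlapping INO80B and WBP1 were 28.0 and 26.1 in the controls and 30.4 and 31.2 in knockdown. Summed with overlapping genes on the same strand, the log2 fold change of CHCHD3 went from -1.34 to -0.323 and that of TMEM265 from -1.68 to -0.125. The genes added to CHCHD3 held 77.2 and 90.1 FPKM in the controls and 76.4 and 89.1 FPKM in knockdown. Those added to TMEM265 held 24.9 and 21.5 FPKM and then 26.8 and 20.6 FPKM. The adjusted p-values of these 9 genes lay between 0.236 and 0.352 in limma. The annotated 3′ UTRs of CHCHD3, HADHB, TIMM17B and CCDC25 contain the heptamer CACTCAC or ACTCACA. Those of CHST11 and HNRNPF contain TCTAAGT or CTAAGTA. So do those of RAB31 and RAP1A among the genes that were higher. This makes 6 of the 10 lower genes and 2 of the 9 higher genes searched, against 26.5% of all genes searched. The heptamers were chosen from these same values. CACTCAC, ACTCACA and TCTAAGT went with lower values in knockdown across genes.

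Higher in both knockdown samples, again without passing the threshold, was RAB31, a small GTPase of vesicle transport (5.56 ± 1.59 FPKM in the controls, 19.3 ± 0.475 FPKM in knockdown). The others were FAM110A (3.15 ± 0.277 and 11.6 ± 0.872 FPKM), KCTD2 (2.36 ± 0.338 and 7.03 ± 0.405 FPKM), PQLC1 (5.61 ± 0.162 and 16.2 ± 1.19 FPKM) and the zinc finger gene ZNF672 (3.26 ± 0.0249 and 9.23 ± 0.388 FPKM). CRABP2, which carries retinoic acid to its nuclear receptor, was at 14.03 ± 0.862 and 34.5 ± 2.32 FPKM. The small GTPase gene RAP1A was at 13.8 ± 0.172 and 29.3 ± 0.772 FPKM. The BMP antagonist gene NBL1 was at 48.1 ± 2.58 and 98.5 ± 5.04 FPKM, and ITM2C at 10.5 ± 0.192 and 19.8 ± 0.252 FPKM. NPIPA5, one of a family of near-identical segmental duplicates, was listed at 0.0143 and 0 FPKM in the controls and 3.41 and 2.58 FPKM in knockdown. The summed FPKM of the 6 NPIPA genes were 16.9 and 7.75 in the controls and 18.2 and 13.6 in knockdown. Adjusted p-values of these 10 genes lay between 0.251 and 0.352 in limma.

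**Figure D2:**
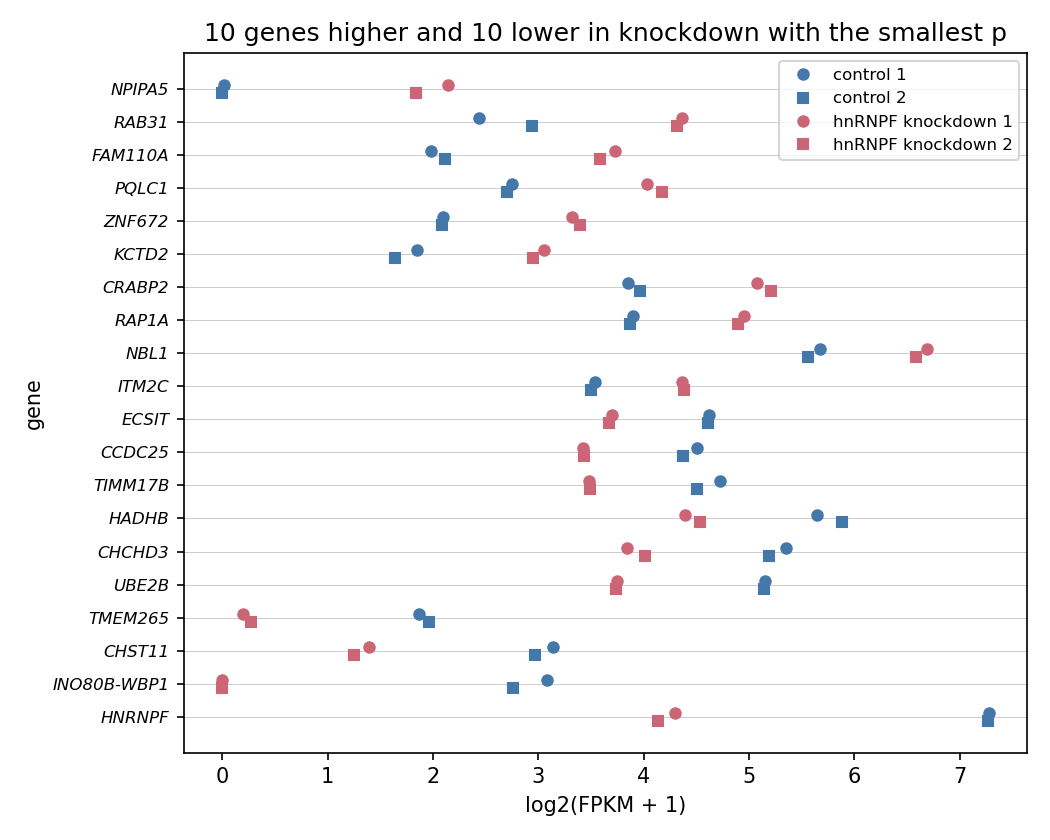
Values per library on the log2(FPKM + 1) scale (horizontal axis) of the 10 genes higher and the 10 genes lower in knockdown with the smallest p, ordered by fold change; colours and symbols mark the group and replicate. The knockdown samples lie beyond both controls for each gene, and HNRNPF alone passed the adjusted threshold (adjusted p = 0.0251).

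Regulators and markers of the epithelial and mesenchymal states, chosen in advance, showed no difference that passed the threshold. The epithelial splicing regulators ESRP1 (38.5 ± 0.671 FPKM in the controls, 39.2 ± 0.424 FPKM in knockdown) and ESRP2 (19.4 ± 3.09 and 20.1 ± 2.74 FPKM) overlapped between the groups. So did total CD44 (368 ± 30.5 and 355 ± 18.3 FPKM), a cell surface receptor whose isoforms switch in the epithelial-mesenchymal transition. Log2 differences between the groups had 95% intervals of -0.21 to 0.26 for ESRP1 and -0.35 to 0.24 for CD44. RBFOX2 was at 38.6 ± 1.01 and 43.7 ± 4.21 FPKM. CDH1, which encodes E-cadherin, was at 37.6 and 48.1 FPKM in the controls, 46.0 FPKM in knockdown 1 and 90.0 FPKM in knockdown 2. EPCAM was at 51.2 ± 7.41 and 38.8 ± 0.202 FPKM. Among mesenchymal genes, VIM was at 211 ± 3.39 and 167 ± 5.8 FPKM and FN1, fibronectin, at 1266 ± 123 and 1793 ± 440 FPKM, with adjusted p-values of 0.724 and 0.859 in limma. SNAI2 (17.9 ± 3.02 and 18.1 ± 1.93 FPKM) and TGFB2 (1.58 ± 0.584 and 1.1 ± 0.00971 FPKM) completed the set. CDH2 and ZEB1 stayed under 0.42 FPKM in all 4 samples, and CD24 is not listed.

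Proliferation genes were lower in the knockdown samples as a group. Of the 43 tested, 37 had a log2 fold change below 0, both knockdown samples lay below both controls for 23, and the median log2 fold change was -0.20 (camera, adjusted p = 1.61e-08). With an estimated correlation the adjusted p was 0.657. No single member passed, over all genes or when adjusted over the list alone. HMMR, a mitotic spindle protein gene (21.8 ± 0.167 FPKM in the controls, 12.6 ± 0.814 FPKM in knockdown), and RRM2, a ribonucleotide reductase subunit (78.7 ± 3.24 and 52.4 ± 6.28 FPKM), had the smallest p. The genes of the unfolded protein and amino acid responses were likewise lower, with 27 of 30 below 0 and a median of -0.12 (camera, adjusted p = 2.13e-06; adjusted p = 0.495 with an estimated correlation). TRIB3, a pseudokinase gene induced by ATF4 (39.9 ± 2.35 and 19.6 ± 2.04 FPKM), and SLC3A2, the heavy chain of amino acid transporters (244 ± 6.62 and 168 ± 5.07 FPKM), were the 2 lower members when adjusted over the list alone, against 0 over all genes. Both lists had negative medians in each of the 4 pairs of a knockdown and a control sample, and passed without any 1 sample.

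The p53 target genes were also lower, with 14 of 21 below 0 and a median of -0.18 (camera, adjusted p = 0.00244; adjusted p = 0.653 with an estimated correlation). So were the hypoxia and glycolysis genes, with 23 of 30 below 0 and a median of -0.11 (camera, adjusted p = 0.00844; adjusted p = 0.657 with an estimated correlation). FDXR (14.01 ± 0.0255 FPKM in the controls, 9.86 ± 0.543 FPKM in knockdown) and GDF15 (18.7 ± 3.36 and 11.1 ± 2.02 FPKM) led the p53 list. The glycolytic enzyme genes PFKL (45.6 ± 2.5 and 34.7 ± 1.66 FPKM) and ENO1 (1135 ± 39.7 and 949 ± 56.7 FPKM) led the other. The p53 call was lost without knockdown 1 (adjusted p = 0.325), and the hypoxia and glycolysis call without control 2 (0.513) or knockdown 1 (0.853). Cytosolic ribosomal protein genes passed as lower by a small amount, with 60 of 76 below 0 and a median of -0.05 (camera, adjusted p = 0.00271; adjusted p = 0.657 with an estimated correlation). Their direction turned without control 2 (adjusted p = 0.95) or without knockdown 1 (adjusted p = 0.388). RPS13 (467 ± 21.7 and 351 ± 36.6 FPKM) and RPL6 (757 ± 60.4 and 624 ± 40.0 FPKM) had the smallest p. The ribosomal list also passed in the division by replicate number, higher in number 2 (median 0.0944, camera, adjusted p = 4.73e-15). So did the hypoxia and glycolysis list, again higher in number 2 (median 0.0823, camera, adjusted p = 4.45e-05).

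Epithelial junction and polarity genes were higher in knockdown as a group, with 24 of 33 above 0 and a median of 0.09 (camera, adjusted p = 0.00271; adjusted p = 0.495 with an estimated correlation). DSP, which encodes desmoplakin, was at 139 ± 4.74 FPKM in the controls and 185 ± 6.57 FPKM in knockdown. The tight junction gene CLDN4 was at 2.07 and 0.144 FPKM in the controls against 14.3 and 6.14 FPKM in knockdown. The call was lost without control 1 (adjusted p = 0.0532) or knockdown 2 (adjusted p = 0.0645). The basal mammary markers had 15 of 20 members above 0 and a median of 0.14 (camera, adjusted p = 0.0246; adjusted p = 0.657 with an estimated correlation). They were led by MME (1.84 ± 0.447 and 3.49 ± 0.00371 FPKM) and the keratin gene KRT17 (1274 ± 423 and 1978 ± 271 FPKM). The basal markers also passed in the division by replicate number, higher in number 2 (median 0.235, camera, adjusted p = 0.000122). Their direction turned without control 1 (adjusted p = 0.909). The call was also lost without knockdown 2 (0.665), with median-ratio scaling (0.0672), with no filter (0.068) and once a GC and length trend was removed (0.0915), a correction chosen after seeing the data.

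Replication-dependent histone genes, listed to follow polyA selection, were higher for 7 of 8 members with a median of 0.32 (camera, adjusted p = 0.000465; adjusted p = 0.495 with an estimated correlation). Of these, 2 members were higher when adjusted over the list alone. HIST1H2BK was at 27.7 ± 1.91 FPKM in the controls and 41.1 ± 0.256 FPKM in knockdown, and HIST1H1C at 11.9 ± 1.01 and 17.0 ± 0.011 FPKM. The call was lost without control 1 (adjusted p = 0.0566) or knockdown 2 (adjusted p = 0.0756). Control 2 set the values of 2 further lists. Mitochondrially encoded genes, a marker of RNA quality, passed as higher with 13 of 13 above 0 and a median of 0.21 (camera, adjusted p = 0.00844; adjusted p = 0.657 with an estimated correlation). However, their median in knockdown 1 was 0.38 above control 2 and -0.01 from control 1, and without control 2 the adjusted p was 0.544. The call was also lost without knockdown 2 (0.298), with median-ratio scaling (0.0597) and with no filter (0.0698). MT-CO3 stood at 3291 and 2669 FPKM in the controls and 3583 and 3589 FPKM in knockdown, and MT-ND1 at 807 ± 98.8 and 957 ± 4.53 FPKM. Interferon-stimulated genes had 23 of 30 members above 0 and a median of 0.19 (camera, adjusted p = 0.00844; adjusted p = 0.657 with an estimated correlation). They lost the call without control 2 (adjusted p = 0.889) or knockdown 2 (adjusted p = 0.0947). IFI6 was at 4.32 and 5.06 FPKM in the controls and 8.19 and 19.4 FPKM in knockdown, and SAMD9 at 5.26 ± 0.68 and 7.98 ± 0.74 FPKM. The interferon and mitochondrial lists also passed in the crossed division, lower in control 2 and knockdown 1. Their medians there were -0.158 and -0.215 (camera, adjusted p = 2.67e-05 and 0.000282), with smaller adjusted p-values than for the knockdown.

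**Figure D3:**
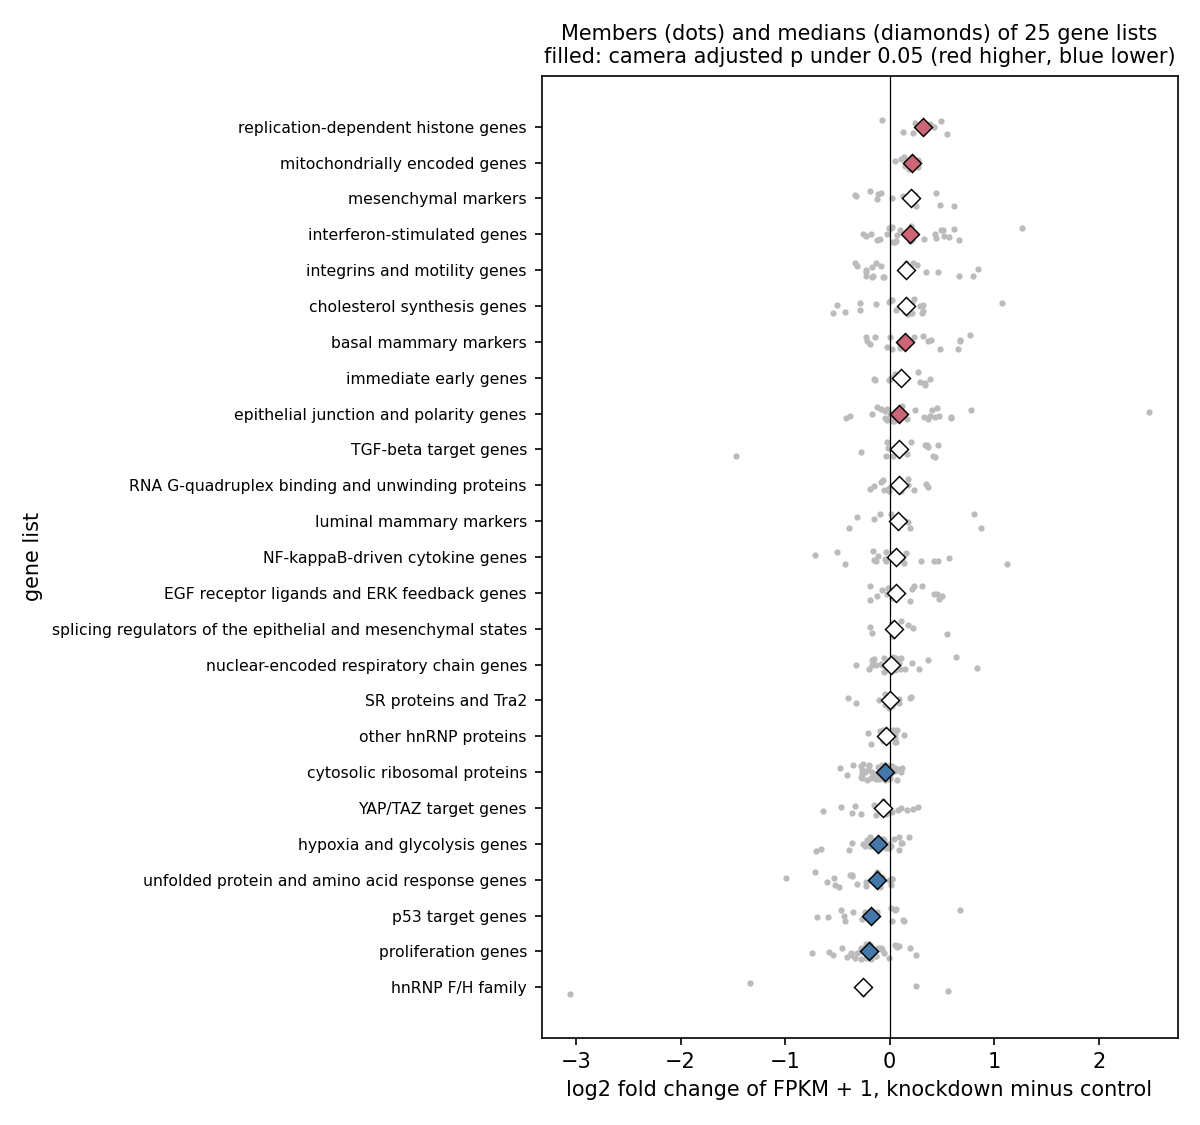
Log2 fold changes of FPKM + 1, knockdown minus control (horizontal axis), of the members (grey dots) of 25 gene lists, with diamonds at the medians; filled diamonds passed camera at the preset correlation, red higher and blue lower in knockdown. The medians of the 10 lists that passed lie between -0.20 and 0.32, and proliferation genes have the lowest of these.

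The other 15 tested lists did not pass. Among RNA-binding proteins, the median was -0.03 for 23 other hnRNP proteins, where HNRNPUL2 (37.6 ± 1.64 and 32.4 ± 2.13 FPKM) and HNRNPA1 (315 ± 25.8 and 280 ± 32.4 FPKM) had the smallest p. It was -0.00134 for 13 SR proteins and Tra2 (SRSF4 at 23.9 ± 2.79 and 17.9 ± 1.6 FPKM; TRA2A at 22.7 ± 3.54 and 18.04 ± 3.68 FPKM). It was 0.04 for 12 splicing regulators of the epithelial and mesenchymal states (MBNL1 at 29.7 ± 0.373 and 26.1 ± 0.168 FPKM), and 0.09 for 16 RNA G-quadruplex binding and unwinding proteins. Mesenchymal markers had a median of 0.20 over 17 genes, with COL5A2 at 6.24 ± 1.12 and 10.01 ± 0.426 FPKM. That of luminal markers was 0.08 over 11 genes, with KRT23 at 0.862 ± 0.0965 and 2.30 ± 0.791 FPKM and KRT18 at 174 ± 2.96 and 133 ± 17.3 FPKM. Of 18 TGF-beta target genes, with a median of 0.09, the receptor gene TGFBR1 was lower when adjusted over the list alone (12.4 ± 2.2 and 3.79 ± 0.561 FPKM). Its 3′ UTR holds TCTAAGT or CTAAGTA, as do those of AXL, SRSF4, MBNL1 and KRT18, and the 3′ UTRs of RRM2 and MBNL1 hold CACTCAC or ACTCACA. INHBA was at 50.4 ± 5.47 and 69.5 ± 2.97 FPKM. Of 19 YAP/TAZ target genes, with a median of -0.06, 2 were lower when adjusted over the list alone. They were NT5E (77.6 ± 1.31 and 55.9 ± 1.27 FPKM) and the receptor tyrosine kinase gene AXL (58.0 ± 6.45 and 36.9 ± 2.3 FPKM). Of 23 NF-kappaB-driven cytokine genes, with a median of 0.06, CXCL5 was higher when adjusted over the list alone (0.736 ± 0.152 and 2.77 ± 0.291 FPKM). TNF was at 8.09 ± 0.288 and 5.43 ± 0.59 FPKM.

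The median was 0.06 for 18 EGF receptor ligands and ERK feedback genes (TGFA at 29.3 ± 3.41 and 41.8 ± 5.47 FPKM; EREG at 11.6 ± 1.32 and 16.2 ± 1.91 FPKM) and 0.11 for 13 immediate early genes (IER2 at 10.7 ± 0.68 and 14.3 ± 2.16 FPKM). It was 0.15 for 25 cholesterol synthesis genes (MVK at 25.6 ± 0.572 and 18.8 ± 1.47 FPKM) and 0.15 for 27 integrins and motility genes (ANXA1 at 303 ± 15.9 and 385 ± 15.6 FPKM; ITGAV at 45.0 ± 0.451 and 54.0 ± 2.11 FPKM). It was 0.01 for 38 nuclear-encoded respiratory chain genes (NDUFA13 at 44.7 ± 6.85 and 69.4 ± 0.993 FPKM; SDHA at 66.8 ± 5.23 and 81.3 ± 2.06 FPKM). Several of these lists passed when 1 sample was left out. Without control 2, camera gave adjusted p-values of 0.000355 for the cholesterol genes and for the EGF receptor ligands, 0.00422 for TGF-beta targets, 0.00609 for immediate early genes and 0.0105 for integrins and motility genes, all higher in knockdown. Without knockdown 1 these were 0.00357 for the cholesterol genes, 0.000881 for TGF-beta targets, 0.00169 for immediate early genes and 0.0109 for integrins and motility genes, and 0.0397 for mesenchymal markers. TGF-beta targets also passed with no filter (adjusted p = 0.0394), with a filter at 5 FPKM (0.041) and with the replicate number as a block (0.0283), EGF receptor ligands with no filter (0.0465) and cholesterol genes with quantile normalization (0.0432). Markers of cell types outside the culture were low. Of 16 leukocyte markers 2 reached a mean of 1 FPKM, led by CD68 at 11.7 FPKM, and of 11 endothelial markers listed, 1 did, ENG at 16.1 FPKM. Their sums were 15.1 and 15.7 FPKM in the controls against 14.7 and 14.5 FPKM in knockdown for leukocyte markers. They were 15.4 and 15.4 FPKM against 18.2 and 16.3 FPKM for endothelial markers.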

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

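The knockdown of HNRNPF kept its direction under all alternatives, with log2 fold changes between -3.13 and -2.98 when each sample was left out in turn, but its call depended on the setting. At a log2 fold change of -3.05 it was not past the threshold with no filter (adjusted p = 0.259), where more genes are tested, or without the intensity trend (0.0995; the cause was not tested), and the number of lower genes was then 0. Over all its alternatives the adjusted p lay between 0.0124 and 0.262, and the call was lost in 5: these 2, the replicate block, and without control 1 (0.262) or control 2 (0.104). When each sample was left out in turn, the number of lower genes lay between 0 and 1, that of higher genes between 0 and 1, and that of gene lists past the threshold between 6 and 12 against 10, with fewer samples in each fit and the lone sample of a group assumed to vary like the other group. The number of lists past the threshold was 0 with an estimated inter-gene correlation. It was 1 with fry, which tests another hypothesis and called the family that holds HNRNPF. The estimated correlation exceeds the preset 0.01 in 21 of 25 lists. A higher correlation is not the whole reason for the lost calls. The estimates were -0.0186 for the epithelial and -0.0567 for the histone list, with unadjusted p-values of 0.0594 and 0.053 in camera. That version rests on 2 residual degrees of freedom, so failing it does not show that a call is false. With the replicate block, HNRNPF had a log2 fold change of -3.05 and an adjusted p of 0.164 on fewer residual degrees of freedom, 0 genes were lower, 1790 genes had an unadjusted p under 0.05 against 797, and 11 lists passed against 10, with TGF-beta targets gained (0.0283). The labels give the groups the same numbers without saying what a number marks, the 2 pairs of samples deviated together with a correlation of 0.39 across genes, and with 2 pairs the samples were treated as sharing only a number.

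With no filter the SR proteins (adjusted p = 0.958) and the respiratory chain genes (0.963) changed direction, and with a filter at 5 FPKM the SR proteins (0.98) and luminal markers (0.935) did; the cause was not tested. When each sample was left out, the lists that turned direction in at least 1 fit had adjusted p-values from 0.207 to 0.688 (SR proteins), 0.0566 to 0.772 (other hnRNP proteins), 0.0397 to 0.896 (mesenchymal), 5.93e-06 to 0.909 (basal), 0.000881 to 0.909 (TGF-beta targets), 0.216 to 0.909 (NF-kappaB), 0.000355 to 0.773 (EGF receptor ligands), 0.00169 to 0.82 (immediate early), 0.000355 to 0.981 (cholesterol), 0.0105 to 0.773 (integrins and motility), 3.84e-09 to 0.95 (ribosomal) and 0.156 to 0.822 (respiratory chain). The log2 fold changes that turned lay between -0.732 and 0.23 (GRSF1), -0.136 and 0.0326 (CD44), -0.105 and 0.206 (ESRP2), -0.146 and 0.181 (SNAI2), and -0.0766 and 0.364 (CSF1R, a leukocyte marker). Of 1137 comparisons of a named gene other than HNRNPF with its main value, 1129 kept direction and side of the threshold; of 350 such comparisons of a list, 295 did, 22 changed direction, 20 lost the call (3 of them with a change of direction) and 16 gained it. At the implied depth 1 FPKM on 1 kb is about 77 to 85 fragments, and whether depth limits the values of low genes was not tested.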

Other observations

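The test of depth was chosen after the result was seen, as were the comparison with the change of overlapping genes, the comparison of called lists across divisions, the GC and length correction, the follow-up of single sequences in 3′ UTRs and the genes named for the division by number.

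Samples that share a replicate number resembled each other across the groups. Of the 3 ways to divide 4 samples 2 against 2, the division by number separated 6613 genes (50.4%) without overlap. The division by knockdown separated 4536 (34.6%) and the crossed division 1958 (14.9%). Samples that all resembled each other equally would give 33.3% each, and a large share in 1 division lowers the others. Genes without overlap at least 1 apart in mean log2(FPKM + 1) numbered 155, 70 and 33. Higher in the number 1 samples were PDXP (6.26 and 5.75 FPKM against 0.12 and 0.0991 FPKM in the number 2 samples), NKTR (17.9 and 16.8 against 6.30 and 6.51 FPKM), the RNA helicase gene DDX17 (79.3 and 76.6 against 44.2 and 45.2 FPKM) and the splicing factor gene RBM5 (31.2 and 31.5 against 17.4 and 17.3 FPKM). Higher in the number 2 samples were FOSL2, an AP-1 subunit (5.59 and 5.25 FPKM in number 1 against 19.3 and 18.9 FPKM), RPS23 (366 and 355 against 655 and 632 FPKM), the citrate synthase gene CS (38.7 and 37.1 against 76.8 and 71.0 FPKM) and the autophagy gene GABARAP (27.4 and 30.6 against 73.5 and 62.3 FPKM). Each value pair gives the control and then the knockdown sample. Of these 8 genes PDXP passed (limma, adjusted p = 0.0403) and the other 7 did not (0.0866). Camera called 11 lists in this division, all higher in number 2, against 10 in the knockdown division and 4 in the crossed one.

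The count of genes above 0 FPKM argues against depth alone as the cause of this resemblance, but cannot exclude a part for it. The number 1 samples have fewer implied fragments yet list 1094 and 1143 more genes above 0 FPKM than the number 2 samples in the same groups. This count also depends on which RNA a library holds, so it does not isolate depth. Among genes of at least 50 FPKM, where depth matters least, the division by number separated 1.08 times as many genes as the knockdown, against 1.46 times over all tested genes. This ratio was the depth test first written down; it decided nothing, and the test on genes above 0 FPKM replaced it. With a GC and length trend removed, the ratio of genes separated by number to those separated by knockdown was 1.36, against 1.46 as deposited, so such a trend is not the whole cause. A larger share of nuclear or unspliced RNA in the number 1 samples stays open. The 12 tested members of a list of nuclear-retained RNAs and of genes with detained introns, MALAT1 and CCNL2 among them, had a median log2 difference of -0.382 (number 2 minus number 1), lower for 12 of 12 and at the 0.1 percentile of 10000 random lists. Noncoding genes, however, lay only -0.0994 from protein-coding ones. No biological explanation was tested, and the labels do not say what a number marks.

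The genes without overlap between the groups and at least 1 apart in mean log2(FPKM + 1) numbered 70, with 35 higher and 35 lower. Low genes over 2-fold apart in FPKM can fall outside this count. Values may have moved between overlapping or near-identical genes for INO80B-WBP1, whose sum with its partners differed by 0.183 (log2), and for NPIPA5, where the sum of its family differed by 0.42. Over all 70 genes, 78.6% stayed at least 1 apart once overlapping genes on the same strand were summed, which leaves such moves open. Of the 70, 20 overlap a gene of at least 1 FPKM, and 13 of these came under 0.5 in the sum, CHCHD3 (-0.323) and TMEM265 (-0.125) among them. A sum also comes nearer 0 when a gene that did not move is added. The overlapping genes moved the opposite way by at least 50% of the gene's own FPKM change for 5 of the 20. For CHCHD3 this change was -23.4 FPKM and that of the gene added -0.927 FPKM, and for TMEM265 they were -2.6 and 0.505 FPKM, so these values show no matching gain for CHCHD3. For the lower genes, a candidate explanation that stays open is silencing of other transcripts through seed matches of a hairpin. Of 16169 heptamers in 3′ UTRs, CACTCAC went most strongly with lower values in knockdown (z = -9.66, 1106 genes). It ranked 1 in both same-numbered pairs and exceeded the most negative z of the other divisions (-4.43 and -3.91). The most positive z was 6.15 in the division by number, 4.56 in the crossed one and 4.13 in that by knockdown. A z of about 6 in size thus also arose in a division that does not contrast the groups.

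ACTCACA (z = -7.28) and TCTAAGT (z = -6.64) came next. Where CACTCAC was followed by A and TCTAAGT and CTAAGTA were absent, 277 genes had a median log2 fold change of -0.09, against -0.03 for 577 genes with CACTCAC but not that A. The median was 0.01 for the 8298 genes with none of the 4 heptamers. The heptamers were chosen from these same values, so a lower median with them is partly built in and is no separate evidence. In the longest HNRNPF transcript TCTAAGT occurs at position 1987, in the 3′ UTR, and the reverse complement of CACTCAC at position 1676, upstream of the 3′ UTR. By comparison, 26.7% of all heptamers tested occur there on either strand. Hairpin sequences are not given in the sources used here, and binding of these heptamers by a protein was not tested.

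The lower values of proliferation genes and stress response genes in knockdown were weighed against 3 technical explanations. After a GC and length trend was removed, the medians were -0.192 and -0.141 and both lists passed (adjusted p = 4.16e-06 and 5.7e-06), so that trend is not the whole cause. The medians were negative in 4 of 4 pairs of a knockdown and a control sample for both lists, which argues against a leak of the division by number as the whole cause. The camera call of the proliferation list is not particular to the knockdown, since that list also passed in the division by number (higher in number 2, median 0.0484, adjusted p = 0.000224) and in the crossed one (lower in control 2 and knockdown 1, median -0.0644, adjusted p = 0.0176). The stress response list did not pass there (adjusted p = 0.78 and 0.263). Of the 10 lists called for the knockdown, 7 were called in at least 1 other division. They were the proliferation, ribosomal, hypoxia and glycolysis, basal, histone, mitochondrial and interferon lists. Without members that hold a seed site the medians of the proliferation and stress response lists were -0.172 and -0.123. Matches to the heptamers chosen above are therefore not the whole cause. The hairpin sequences are not known, so other direct seed matches stay open. Lower expression of these genes with loss of hnRNPF is thus a hypothesis, found and tested on the same data. The lists did not pass in camera with an estimated correlation (adjusted p = 0.657 and 0.495), a version with little power on 2 residual degrees of freedom. An indirect effect of the hairpin stays open.

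A hypothesis that transcripts rich in G-runs, the sequence hnRNP F binds, change in abundance found no backing. Across 12955 genes, which are not independent replicates, Spearman's rho between G-runs per kb and the log2 fold change, with GC content and length held constant, was -0.00712, smaller in size than the -0.0322 of the crossed division. A hypothesis of copy number differences between the lines was weighed by the median log2 fold change of each chromosome. In a permutation of genes, 2 of 23 chromosomes passed, chromosome 19 (0.0238, adjusted p = 0.017) and chromosome 8 (-0.0297, adjusted p = 0.0407). The largest median was 0.0308 (chromosome 20, 349 genes, adjusted p = 0.0718). With the middle chromosome's median subtracted the largest shift was 0.0314, against 0.0302 in the other divisions treated alike, so shifts of this size also arise in a division that does not contrast the groups. No median reached the 0.1 set beforehand, and smaller changes stay open.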
